A study of Mus musculus with 2 samples.

How the data were processed

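Ribosomal-RNA-reduced, stranded total RNA libraries with ERCC spike-ins were made from mouse hippocampus, per the labels, and 2 libraries of one group were analysed. The build is mm10, per the labels, and the annotation is GENCODE M21, per the deposited notes. The aligner and its version are not given in the sources used here. For each library the authors deposited a gene table and a transcript table with expected counts, TPM and, per transcript, the percent of its gene's TPM. These have the RSEM column format and were made from transcriptome alignments, per the deposited notes. A second deposited transcript table holds estimated counts and TPM in the kallisto format and was made from reads, per the deposited notes. RSEM-format effective lengths of spike-ins were 99 bases under their lengths, and in the second table transcripts over 3000 bases lost a median of 347 and 343 bases in replicates 1 and 2.

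The gene table had 81881 rows, of which 55536 were annotated genes, 26248 tRNA rows, 96 spike-ins and 1 phiX row. All 55536 gene identifiers matched the GENCODE M21 annotation, from which names, classes and coordinates were taken. No row of the second table was found for 86 annotated genes. Spike-ins took 0.376% and 0.429% of expected counts in replicates 1 and 2. Depth was 34919989 and 41206890 expected counts. Intervals and floors cover counting error only.

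TPM was used as deposited for levels, with n = 2. Ratios of the libraries used genes with at least 200 expected counts over both, and a library with fewer than 3 counts was set at a floor of 3 counts. No ratio was taken where both libraries were under the floor. Counting intervals are exact Clopper-Pearson 95% intervals of the counts, scaled to the TPM ratio. Lists were compared on log2(TPM + 1), which understates the change of low genes. Each list's median was set against 10000 random lists of the same size, drawn within 25 bins of mean expression. The labels give the replicates separate biosamples and the same donor entry. edgeR 4.0.16 gave the biological coefficient of variation with an intercept-only design on expected counts rounded to whole numbers, with TMM factors, for genes with at least 20 counts. DESeq2 1.42.0 gave size factors. Other work used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. With 1 group and 1 library against 1, no test between groups exists and no p-values are given.

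The design, the lists, the naming rule and the alternatives, apart from those named as chosen later, were fixed before the data were examined. The rule names 2 to 6 members per list by highest mean TPM plus members against their list, the top 15 nuclear protein-coding genes, the 10 largest log2 ratios in each direction among genes with at least 200 counts, and 20 genes chosen for transcript shares. Some genes that the rule names are not reported here. Alternatives were the second quantification, TPM rescaled over nuclear protein-coding genes, TMM, DESeq2 and spike-in scaling, other pseudocounts, filters and thresholds, and each replicate alone.

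The ratio rule was tested on simulated counts for the 12962 genes of the library comparison with 200 genes changed in replicate 2. All 4-fold increases were called, and 88% of the 50 genes lowered 4-fold. The other 6 fell under the 200-count minimum after the change, and 100% of those still above it were called. Of 1.5-fold increases and decreases 4% each passed the 2-fold rule, and 0 unchanged genes were called. Of 100 lists of 10 unchanged genes, 5 lay outside the central 95%. Simulated genes varied independently, with the common coefficient of variation of 0.0993 of these libraries, and levels followed counts alone. Shifts of effective length or read assignment and co-expression within lists were left out, so these rates need not hold for the real calls.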

Results

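Total RNA was sequenced from the hippocampus of female mice at 25 days of age, labelled as a layer of hippocampus. The strain, B6CASTF1/J, is an F1 hybrid of C57BL/6 with the wild-derived CAST strain. The labels give a single group with biological replicates 1 and 2, each library made from 300 ng of RNA with ERCC spike-ins added. They give separate biosamples for the replicates and the same donor entry for both. The gene tables held 34919989 expected counts for replicate 1 and 41206890 for replicate 2. There is no second group, so the account below describes RNA levels in this tissue and then compares the 2 libraries with each other. Levels are TPM, given as mean ± SD over the 2 libraries (n = 2) unless each library is named, and coordinates are on mm10.

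The protein-coding RNA of highest level came from housekeeping, neuronal and glial genes alike. Of nuclear protein-coding genes, Actb (ENSMUSG00000029580.14, chromosome 5, 142903115 to 142906754), encoding cytoplasmic beta-actin, stood first at 1510 ± 14.9 TPM. Camk2a (ENSMUSG00000024617.16, chromosome 18, 60925618 to 60988152), the alpha subunit of the calcium/calmodulin-dependent kinase of excitatory synapses, followed at 1463 ± 161. Their order was reversed in replicate 1, where Camk2a was at 1577 TPM and Actb at 1499. In the second deposited quantification Gapdh, at 3513 and 3879 TPM, was above Actb, at 3027 and 3346. Cpe, a prohormone-processing enzyme, reached 1306 ± 29.2, Eef1a1, a translation elongation factor, 1302 ± 57.8, and Fth1, ferritin heavy chain, 1274 ± 32.0. Apoe, the main lipid carrier made by astrocytes, was at 1116 ± 11.4, and Hpca, a calcium sensor named for the hippocampus, at 1108 ± 92.7. Aldoa had 1077 ± 47.4, Cst3 1036 ± 35.3 and Gapdh 1033 ± 53.4. Also among the top 15 were Snurf at 1024 ± 42.3, Calm3 at 1007 ± 23.6, Hspa8 at 991 ± 16.7 and Mbp, myelin basic protein, at 981 ± 9.31. Snurf overlaps Snrpn and is listed at 0 TPM in both libraries of the second deposited quantification, so its level is uncertain.

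Markers of each hippocampal field were present. Among CA1 pyramidal neuron markers, Wfs1 reached 83.8 ± 8.19 TPM, Mpped1 71.9 ± 0.226, Ccn3 53.0 ± 7.35 and Fibcd1 52.1 ± 4.79. CA2 markers were led by Pcp4, a calmodulin regulator, at 123 ± 6.82 and Rgs14 at 41.6 ± 2.36, and Map3k15 was under 1 TPM in both libraries. CA3 markers were led by Cpne4 at 49.3 ± 4.38 and Bok at 34.3 ± 5.06. Among dentate granule cell markers, Calb1 was at 61.2 ± 4.55, Prox1, the transcription factor that maintains granule cell identity, at 41.9 ± 5.62 and C1ql2 at 35.4 ± 1.41. Levels in tissue RNA do not tell, for any of these lists, which cells made the RNA. The list of dentate neurogenesis markers was lower, and the same limit holds for it. Calb2 was at 20.8 ± 2.38, Neurod1 at 14.6 ± 1.82 and Dcx, a microtubule protein of migrating neurons, at 8.67 ± 0.113. Proliferation genes were lower still, with Top2a at 1.74 ± 0.127 and Mki67 at 0.78 ± 0.0707. Subiculum markers Lxn and Fn1 were at 20.9 ± 0.622 and 14.9 ± 2.14.

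Excitatory neuron RNA outweighed that of inhibitory interneurons. The 7 glutamatergic markers summed to 3123 ± 282 TPM, with Nrgn at 724 ± 46.2 and Slc17a7, the vesicular glutamate transporter VGLUT1, at 639 ± 12.6. The 12 GABAergic interneuron markers summed to 831 ± 10.9. Cck, which pyramidal neurons also make, had the highest level of these at 299 ± 1.77, before Sst at 183 ± 20.7, the GABA-synthesising enzyme gene Gad1 at 132 ± 6.31 and Npy at 60.2 ± 1.41. Pvalb was at 23.6 ± 0.163 and Vip at 6.68 ± 1.32. These sums depend on the genes listed and are not cell numbers.

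Glial RNA was abundant. Astrocyte markers summed to 2384 ± 15.6 TPM, including the glutamate transporter gene Slc1a2 at 792 ± 67.5, Glul at 687 ± 45.4 and Gfap at 125 ± 6.88. Oligodendrocyte markers summed to 2580 ± 40.8, with the myelin gene Mbp contributing most. Precursor markers reached 163 ± 0.827 in sum, led by Olig1 at 72.2 ± 1.77 and Gpr17 at 32.3 ± 0.24. Microglial markers summed to 202 ± 1.94, with Csf1r at 33.6 ± 0.346 and C1qb at 21.8 ± 1.82. Vascular lists summed to 133 ± 6.84 for endothelium, led by Slc2a1 (39.3 ± 0.898) and Ly6c1 (25.1 ± 0.721), and 68.9 ± 0.219 for mural cells, led by Vtn (25.5 ± 0.721) and Rgs5 (22.6 ± 0.141).

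**Figure D1:**
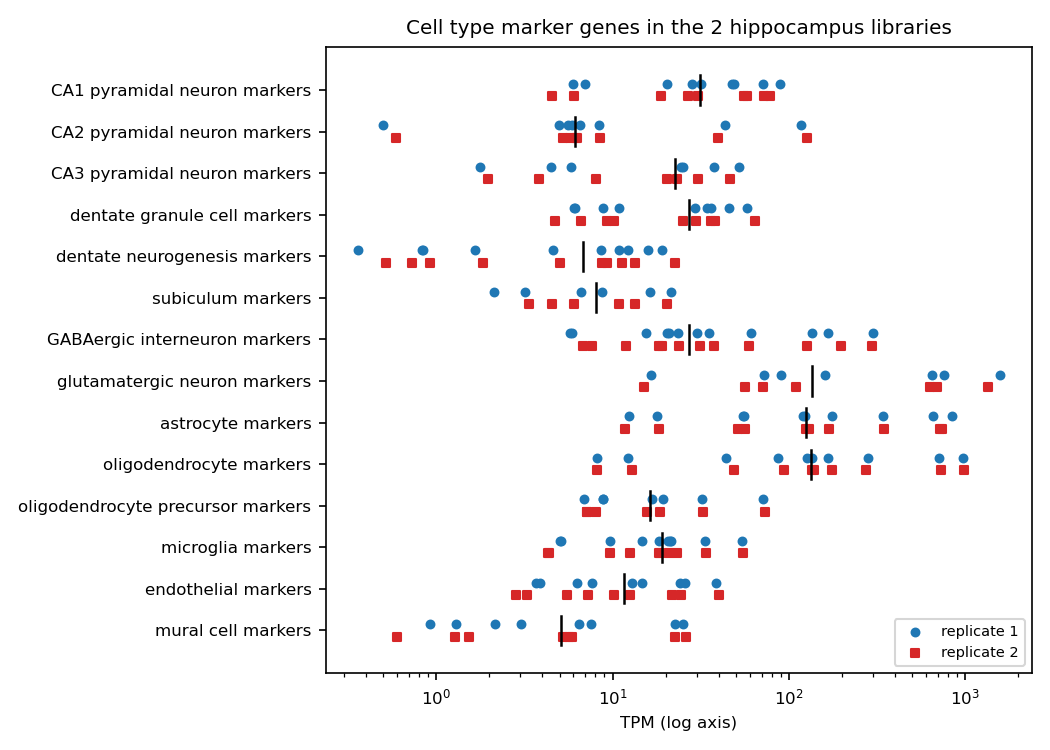
TPM of each cell type marker gene on a log axis, with circles for replicate 1 and squares for replicate 2; each vertical bar is the median of the list's mean TPM. Astrocyte and oligodendrocyte markers have medians of 125 and 134 TPM, and the mural cell markers have a median of 5.10 TPM.

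Lists for tissue next to the hippocampus were also read. Choroid plexus markers included Enpp2 at 71.7 ± 7.97 TPM, a gene that oligodendrocytes also express, and Ttr, the transthyretin made in quantity by choroid plexus, at 39.3 ± 22.4. The other 8 choroid plexus genes were each under 4 TPM. Ependymal markers summed to 9.40 ± 0.707, with Rsph1 at 5.06 ± 0.75 and Foxj1 at 2.18 ± 0.00707. Meningeal fibroblast markers were led by Ptgds at 170 ± 7.86, which oligodendrocytes make too, and Igf2 at 28.0 ± 3.41. Thalamus markers were led by Prkcd at 14.3 ± 4.55 and Rora at 12.5 ± 1.99. Striatum markers were led by Pde10a at 24.4 ± 2.80 and Ppp1r1b at 18.7 ± 2.23, and the dopamine receptor genes Drd1 and Drd2 were at 1.75 ± 0.467 and 1.33 ± 0.255. Neocortex layer markers were led by Etv1 at 33.6 ± 0.0707 and Lamp5 at 19.3 ± 1.31. Blood was represented by globin RNA, with Hba-a1 at 221 ± 4.18 and Hbb-bs at 214 ± 19.5. The globin genes have near-identical copies, so their individual values are uncertain.

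Among AMPA receptor genes Gria1 (283 ± 13.8 TPM) and Gria2 (257 ± 32.8) lay well above Gria3 (61.0 ± 4.85) and Gria4 (22.6 ± 0.82) in both libraries, and Gria1 exceeded Gria2 by less than the SD of Gria2. NMDA receptor RNA was led by the obligatory subunit gene Grin1 at 184 ± 27.8, with Grin2a at 144 ± 29.1 and Grin2b at 136 ± 35.9, whose difference was smaller than their SDs. Kainate receptor RNA was led by Grik5 at 103 ± 16.2 and Grik2 at 36.5 ± 2.57. Of GABA-A receptor genes Gabra5, enriched in hippocampal pyramidal neurons, was at 76.7 ± 3.51. Gabra6, the cerebellar granule cell subunit, was at 0.11 ± 0.0849.

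Among immediate early genes Arc was at 46.1 ± 6.89 TPM, Jun at 40.8 ± 2.39 and Egr3 at 40.4 ± 5.02, which overlapped within their SDs, while Fos was at 6.96 ± 1.87 and Npas4 at 2.73 ± 0.0354. Glucocorticoid-responsive genes were led by the metallothionein genes Mt1 at 306 ± 29.5 and Mt2 at 257 ± 38.8, with Tsc22d3 at 49.6 ± 8.79 and Fkbp5 at 31.8 ± 3.85. The constitutive chaperone gene Hspa8 dominated the heat shock list, and the inducible Hspa1a was at 7.45 ± 0.226. Of 11 interferon-stimulated genes 4 reached 1 TPM in both libraries, the highest being Ifi27 at 33.1 ± 0.318 and Stat2 at 13.1 ± 1.23. Cholesterol synthesis genes were led by Hmgcs1 at 115 ± 1.79.

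Among the 19 listed imprinted genes, the maternally expressed noncoding genes Meg3 at 840 ± 331 TPM and Rian at 412 ± 52.4 were highest. The paternally expressed Snrpn at 366 ± 5.49 and Nnat at 274 ± 41.1 followed. H19 was at 0.29 ± 0.113. Parental alleles were not separated in the tables used, and loss of reads from CAST alleles on the mm10 reference was not examined. The X-inactivation RNA Xist had 29524 expected counts in replicate 1 and 23226 in replicate 2, both labelled female. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y together had 9 expected counts in replicate 1 and 0 in replicate 2, the latter under a floor of 3 counts. In the second deposited quantification their summed TPM was 2.79 in the mean, against 0.055 here.

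By RNA class, nuclear protein-coding genes held 42.7 ± 0.992% of TPM. The RNAs 7SL, 7SK, Rmrp and Rpph1, components of the signal recognition particle, of transcription control and of RNA-processing enzymes, held 37.2 ± 1.04%. TPM divides by length, so these short RNAs had 5.44 ± 0.362% of expected counts, while nuclear protein-coding genes had 78.9 ± 0.0634%. The 7SL genes Rn7s1 and Rn7s2 had equal values of 149997 ± 5971 TPM, so their reads cannot be assigned to one or the other. In the second deposited quantification the 7SL, 7SK, Rmrp and Rpph1 genes held 0.000521% of TPM. Mitochondrial rRNA held 7.96 ± 0.137%, long noncoding RNA 2.78 ± 0.331% and spike-ins 0.727 ± 0.0419%. Mitochondrial protein-coding genes held 2.60 ± 0.171%, led by mt-Co1 at 5348 ± 79.8 TPM and mt-Cytb at 3036 ± 186. These genes share reads with nuclear copies of mitochondrial DNA, and mt-Co2, at 101 ± 40.3, is uncertain for that reason. In the second deposited quantification the class held 4.24% and 4.05% of TPM in replicates 1 and 2. There mt-Atp6, at 8691 and 7368 TPM, was above mt-Cytb, at 5163 and 4987. The class share and the order of its genes are therefore uncertain too.

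One leading transcript carried most of the RNA of some neuronal and glial genes and not of others. The leading transcript held over 50% of the gene's TPM in 12 of the 20 genes examined. App-201 held 91.0 ± 0.191%, Gfap-201 90.4 ± 0.622% and Snap25-201 88.9 ± 1.32%. Clta-205 held 72.5 ± 4.21%, Mapt-204 71.0 ± 3.86% and Mbp-211 69.1 ± 0.163%. Dlg4-203 held 63.8 ± 1.59%, Camk2a-203 62.5 ± 1.85%, Gria1-201 58.5 ± 2.37%, Cdc42-201 58.4 ± 0.594% and Gria2-202 55.8 ± 7.30%. Lower leading shares were found for Bdnf-205 at 46.8 ± 2.15%, Map2-204 at 42.5 ± 0.219%, Grin1-201 at 38.6 ± 0.382%, Ntrk2-202 at 33.9 ± 1.61%, Homer1-207 at 32.0 ± 2.21% and Meg3-203 at 26.8 ± 0.127%. The second deposited quantification named the same leader for 18 of the 20 genes, the exceptions being Grin1 and Meg3. Even so, its share for Mbp-211 was 30.2 ± 1.67% and for Dlg4-203 30.1 ± 1.13%.

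The replicates were next compared with each other. At a TPM of at least 1 in both libraries, 14301 genes were detected, 12694 of them protein-coding. Across these genes Pearson's r of log2(TPM + 1) was 0.992 and Spearman's rho 0.991, and 98.7% of them lay within 2-fold. Genes are not independent replicates, so these values describe the pair. The common biological coefficient of variation from edgeR was 0.0993 over 18468 genes. It was 0.0740 over 14692 nuclear protein-coding genes and 0.135 over 20216 genes in the second deposited quantification, so it depends on the genes and the quantification. The labels leave open whether the replicates are separate animals, and with it whether these values and n = 2 cover variation between animals.

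Nuclear long noncoding RNA was lower in replicate 2. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672), a nuclear speckle RNA, was at 5613 TPM in replicate 1 and 3254 in replicate 2. Meg3 was at 1075 and 606, Snhg11 at 206 and 128, Miat at 105 and 65.9, and Neat1, the scaffold of paraspeckles, at 17.1 and 10.9. All 7 listed genes were lower, although Rmst differed little, at 13.6 and 13.0. The list's median log2 ratio of replicate 2 to replicate 1 was -0.66, at percentile 0 among 10000 random lists matched on mean expression. A difference between single libraries has no replicate check, and these percentiles describe these libraries only.

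Of 35 lists, 11 lay outside the central 95% of their random lists. The 1.75 expected by chance holds only for independent genes, whereas some lists share genes and members of a list can vary together. The random lists were not matched on RNA class, and classes differed between the libraries, as given below. Glutamatergic neuron markers were lower in replicate 2 for 7 of 7 genes (median log2 ratio -0.23, percentile 0.64), with Grin2b at 161 and 110 TPM. NMDA receptor genes were lower for 6 of 7 (median -0.24, percentile 0.455), with Grin1 at 204 and 165 and Grin3a, against its list, at 14.4 and 15.1. In the second deposited quantification this list lay at percentile 9.13, inside the range. Immediate early genes were lower for 11 of 14 (median -0.27, percentile 0.06). Egr1 was at 46.5 and 27.6 TPM and Arc at 51.0 and 41.2, while Jun, Btg2 and Ier2 were higher. Thalamus markers had a median of -0.30 at percentile 1.64, with Prkcd at 17.5 and 11.1, and Ramp3 was the one member not lower. With a pseudocount of 0.1 that list lay at percentile 4.88, inside the range. Mitochondrial protein-coding genes had a median of -0.15 at percentile 0.315, and mt-Co2 and mt-Co3 went the other way. On TMM-scaled counts their percentile was 5.43, inside the range.

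Another 5 lists were higher in replicate 2. Glucocorticoid-responsive genes had a median of 0.22, above all 10000 random lists, with 6 of 10 genes higher. Mt2 was at 229.8 and 285 TPM and Tsc22d3 at 43.4 and 55.8, whereas Zbtb16 was at 50.6 and 41.9, and Sgk1, Per1 and Cdkn1a were also lower. Striatum markers had a median of 0.22 at percentile 99.95 with 7 of 9 higher, while Pde10a and Rgs9 were lower. Red blood cell genes were higher for 5 of 5 (median 0.19, percentile 99.8). Choroid plexus markers were higher for 8 of 10 (median 0.14, percentile 99.8), with Kl and Slc4a5 lower. Subiculum markers were higher for 3 of 6 (median 0.12, percentile 98.9), with Lxn, Fn1 and Slc17a6 lower, so that list did not move as one. The remaining lists lay inside the range, among them the markers of CA1, CA2, CA3, dentate granule cells, interneurons and microglia. On TMM-scaled counts the astrocyte, oligodendrocyte, cholesterol synthesis and imprinted lists also lay above it, at percentiles 98.7, 99.6, 98.5 and 99.6, and the endothelial list also lay below it, at 1.55. The Y-linked list, at 1.15, has too few counts to be read.

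**Figure D2:**
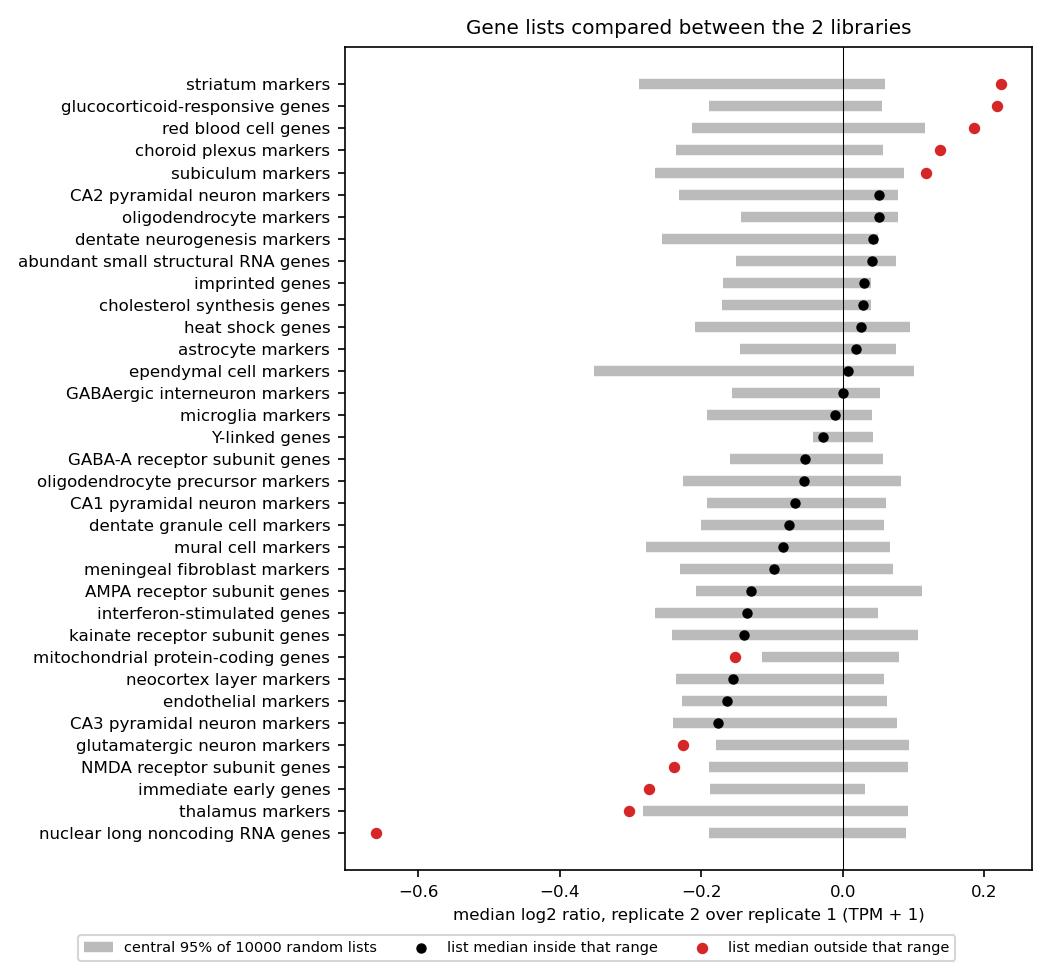
Median log2 ratio of replicate 2 to replicate 1 for each of 35 gene lists on TPM + 1, with grey bars for the central 95% of 10000 expression-matched random lists. The nuclear long noncoding RNA list, at -0.66, lies farthest from its bar, and 11 lists in red lie outside theirs.

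Single genes that differed at least 2-fold were few. Among 12962 genes with at least 200 expected counts over both libraries, 13 were at least 2-fold higher and 94 at least 2-fold lower in replicate 2. The lower genes numbered 52 on TMM-scaled counts, and 169 in the second deposited quantification, 55 of them shared. Of the 94, 67 belonged to the annotation class TEC, gene models that await experimental testing, and 15 were protein-coding. Some of the 94 were lower in TPM with little change in counts, such as Myh7b, with 102 and 110 expected counts at 2.44 and 1.11 TPM. On deposited TPM the largest decreases were in Gm10048, at 2.34 and 0.51 TPM, and in a pair of neighbours at the end of the X chromosome. The log2 ratio of Gm10048 was -2.20, against -1.56 on TMM-scaled counts and -1.31 in the second deposited quantification, where it was not the largest decrease. Gm21887 (ENSMUSG00000095562.7, chromosome X, 170009659 to 170019281) was at 116 and 26.7 TPM, a ratio of 0.229 with a 95% counting interval of 0.203 to 0.259. Mid1 (ENSMUSG00000035299.16, chromosome X, 169685199 to 170005736), a ubiquitin ligase gene that extends into the pseudoautosomal region, was at 11.8 and 3.11, a ratio of 0.264 (0.225 to 0.308). The other 7 of the 10 largest decreases were Gm37006, Gm38056, Gm37814, Gm44667, Gm47135, Gm49069 and Gm47493, with ratios between 0.30 and 0.358.

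Of the 10 largest increases, Ttr (ENSMUSG00000061808.4, chromosome 18, 20665280 to 20674321) was the one with over 1000 counts. It was at 23.5 and 55.1 TPM, a ratio of 2.35 (2.14 to 2.58). Gm10163 and Gm20388 had 0 counts in replicate 1 and, against a floor of 3 counts, were 128.65-fold and 117-fold higher in replicate 2. These are bounds for counting error only and do not cover how reads were assigned. In the second deposited quantification Gm10163 was at 0.109 TPM in replicate 2, against 39.7 here. For Gm20388 the bound in the second deposited quantification was a log2 ratio of 6.18. The others were the small nuclear RNA gene Gm24497 with a ratio of 8.97, Rps12l1 with 6.05, Gm21985 with 6.03, Lbhd1 with 3.51, Gm14308 with 3.04, Tmem254c with 2.81 and Nutf2 with 2.29. In the second deposited quantification 4 of the 13 were also at least 2-fold higher. Lbhd1 had a log2 ratio of 0.44 on TMM-scaled counts, under 2-fold. In the second deposited quantification Ttr had a log2 ratio of 1.29, and Gm21985, Lbhd1, Gm14308, Tmem254c and Nutf2 were under 2-fold. Gm10163, Gm24497 and Rps12l1 had fewer than 3 counts in both libraries and gave no ratio.

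**Figure D3:**
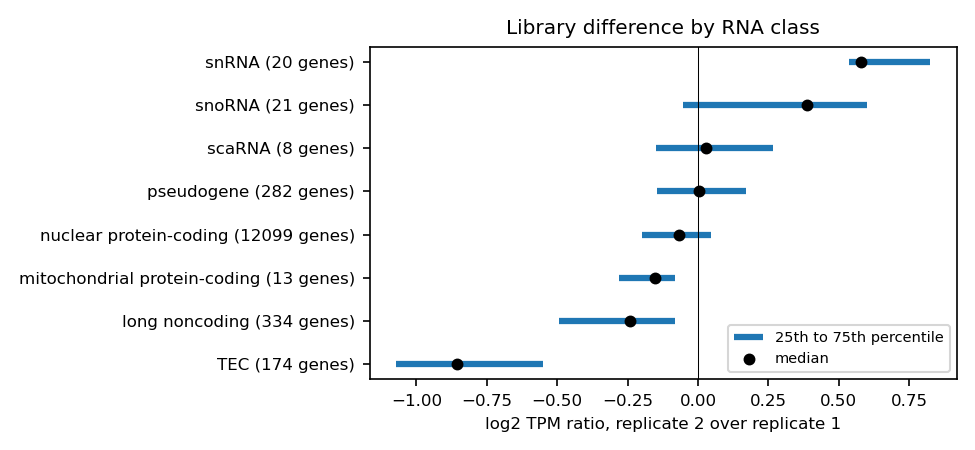
Log2 TPM ratio of replicate 2 to replicate 1 by RNA class, for classes with at least 8 genes at 200 expected counts or more, as the median (dot) and the 25th to 75th percentile (line). TEC genes have a median of -0.86, long noncoding genes -0.24, nuclear protein-coding genes -0.07 and snRNA genes 0.58.

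The difference ran through RNA classes. TEC genes had a median log2 ratio of -0.86, with 169 of 174 lower in replicate 2. Long noncoding genes had a median of -0.24 (281 of 334 lower), nuclear protein-coding genes -0.07, snoRNA genes 0.39 (14 of 21 higher) and snRNA genes 0.58 (20 of 20 higher). The snRNA genes include multicopy families whose reads are shared, and snRNA and snoRNA each held 0% of TPM in the second deposited quantification. The 25 spike-ins with at least 200 counts had a median of 0.10 and an SD of 0.11.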

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

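Rows for tRNA genes, which enter none of the comparisons above, held 6 expected counts in replicate 2, above the 3 that a count of 0 allows, and 1 in replicate 1. They are spread over 26248 rows and no value of a single tRNA gene can be read at this depth. No explanation was tested.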

How the results depend on the processing

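Pearson's r stayed within 0.01 of 0.992 under all 8 alternatives run, a tolerance set for lack of a replicate spread, and the 14301 genes detected and the 267 listed genes at 1 TPM or more moved by less than 1.5 times. Each replicate alone gave 14611 to 15299 genes detected, 269 to 271 listed genes and 12 leading transcripts over 50%. Counts of 2-fold genes depended on the setting. For 13 higher and 94 lower genes, the second quantification gave 20 and 169 (3 and 55 of them shared), a minimum of 20 counts 176 and 1000, a minimum of 1000 counts 1 and 4, and a 1.5-fold rule 72 and 431. TMM and DESeq2 scaling each gave 52 lower genes, and protein-coding genes alone, an alternative chosen after seeing the data, gave 15. Protein-coding genes alone and the minimum of 1000 counts leave fewer genes to test, and the minimum of 20 counts and the 1.5-fold rule admit more. TMM and DESeq2 scale counts alone, whereas deposited TPM also divides by effective length. Myh7b, called lower on TPM at 2.44 and 1.11, had 102 and 110 expected counts. The median log2 ratio over genes was also -0.0716 on deposited TPM and 0.0248 on TMM-scaled counts. How much each adds was not tested, nor was the cause for the second quantification. None of the 10 genes of largest ratio in each direction changed sign under the scalings or in the second quantification where a ratio could be taken; Gm10163, Gm24497 and Rps12l1 gave none in the second quantification. Lists above the central 95% were 5, and 9 under TMM, DESeq2 and spike-in scaling and 8 with random lists matched on length too, also chosen after seeing the data. Lists below were 6, and between 5 and 7 under the alternatives. Of the 11 lists, 8 kept their call under all 8 alternatives. The thalamus list lay inside the range under 3 (percentiles 3.48, 4.88 and 9.74). The NMDA receptor list did so under 1 (9.13) and the mitochondrial list under 3 (5.43 to 5.64). TMM, DESeq2 and spike-in scaling are the same counts times a constant per library. Rescaled TPM is the deposited TPM times such a constant. These constants largely cancel in percentiles and in r, so the 8 are not separate checks. Nuclear protein-coding genes held 42.7% of TPM, 78.9% of expected counts and 73.7% of TPM in the second quantification, an alternative chosen after seeing the data. The 7SL, 7SK, Rmrp and Rpph1 group held 37.2%, 5.44% and 0.000521%, and mitochondrial rRNA 7.96%, 6.93% and 13.0%. List sums in the second quantification were a median of 1.62 times and after rescaling 2.34 times the main values, and 35 of 36 moved beyond their SD under each. Leaving out a replicate leaves no comparison between libraries, so none was run for ratios, r or list differences.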

Other observations

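Of the tests below, those on transcript length, spike-ins, receptor counts per base, the second quantification and choroid plexus genes were chosen after the result was seen, and those on the receptor gene ratio and retained introns before.

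Within the same genes, transcripts annotated as retaining an intron were lower in replicate 2 relative to protein-coding transcripts in 3284 of 3804 genes with at least 100 counts in each class. The median within-gene difference of log2 ratios was -0.49 (95% bootstrap interval over genes -0.51 to -0.47), and -0.48 in the second quantification over 3881 genes. Gria2-206, a retained-intron transcript of an AMPA receptor gene, held 12.5% of Gria2 TPM in replicate 1 and 9.07% in replicate 2.

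The lower nuclear long noncoding RNA of replicate 2 was set against the explanations that follow. Transcript length, and with it a length bias of library making or sequencing, is argued against, since TEC genes lay -0.77 from protein-coding genes of like length, whose 1000 draws had medians between -0.13 and -0.05, and the list itself lay below all 10000 random lists matched on length too. Spike-ins of 505 to 1994 bases decided nothing (Spearman rho with length -0.0531, bootstrap interval -0.46 to 0.39). Another mix of cell types is not decided by the within-gene difference of -0.49, and stays open. Transcripts of the same gene would move alike only if cell types retained introns alike, which was not tested. A lower share of nuclear unspliced RNA in replicate 2 may account for the pattern as a hypothesis, as it predicts a within-gene difference below -0.2 and the value was -0.49. The snRNA genes, with a median of 0.58, went the other way, which a loss of all nuclear RNA alike would not give. They share reads and hold 0% of TPM in the second quantification, so this rests on one quantification. Whether the replicate 1 library held more genomic DNA stays open. The log2 ratio of depth-scaled counts on 1740 olfactory and vomeronasal receptor genes was -0.41, between the limits of -0.5 and -0.25 set for and against it, with a counting interval of -0.55 to -0.28. Of these genes 165 had any count in replicate 1, and the highest gene held 8.56% of the receptor counts. The counts need not come from genomic DNA, so their ratio does not decide the question. Genomic DNA as the whole source of the counts lost is argued against by its amount. The receptor genes had 968 counts in replicate 1, and their counts per base, laid over the listed genes and the TEC genes, make up 0.00354% and 0.968% of the counts these lost. The design names no biological difference between the replicates, so none was tested.

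Reads split differently between near-identical or overlapping genes may account for some of the genes at least 2-fold higher in replicate 2. In the second quantification 4 of 13 were also 2-fold higher, Ttr and Plin4 among them. That count cannot single out read splitting. It includes genes with no ratio there, and a TPM ratio also moves with effective length. Lbhd1 went from 139 to 221 expected counts but from 1.88 to 6.59 TPM. A ratio could be taken there for 10 of the 13, and all 10 were higher. Read splitting is argued against for the genes at least 2-fold lower as a set, of which 58 of 94 were also 2-fold lower and 93 were lower. It stays open for single genes. Nutf2, called higher, had 72.2 and 314 expected counts, and Nutf2-ps1, called lower, had 535 and 334.

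More choroid plexus RNA in replicate 2 remains an open explanation of the Ttr difference. Folr1, Clic6, Kcnj13, Otx2, Slc4a5 and Aqp1 together had 65 counts in replicate 1 and 134 in replicate 2, a ratio of depth-scaled counts of 1.75 (counting interval 1.29 to 2.39). Ttr had a ratio of 2.35, and Enpp2, the list's highest gene, was at 66.1 and 77.3 TPM. Slc4a5 had 8 and 16 counts but 0.26 and 0.12 TPM. These 6 genes were picked from the choroid plexus list after its values were seen, and Kl, another member, was at 3.43 and 3.38 TPM, so their ratio decides nothing. Their counts are low, and Aqp1 and Otx2 are not limited to choroid plexus.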
